A study of Mus musculus with 6 samples.

How the data were processed

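RNA sequencing measured 6 skin scar libraries of C57BL/6 mice, 3 hypertrophic (HS) and 3 normal (NS), 2 weeks after surgery. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into libraries with a low-input kit and read as 150 bp paired ends. Groups and replicate numbers were taken from the sample titles and the group and treatment labels.

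The authors' deposited table held raw counts per gene, per the file headers, in whole numbers that were not normalized. Per the submitters' processing notes, the tools were cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1 and edgeR, with the mouse build mm10; their settings, and whether library and counting kept the strand, are not given in the sources used here. The table listed 17572 genes, each protein-coding and with at least 1 count over the 6 libraries. Long non-coding and other RNA classes were not analysed here. The 6 columns of the authors' normalized values were not used. Gene symbols are those of the table, with the current symbol in parentheses where it differs. Coordinates, 1-based, are those of the GENCODE annotation of the same build, which 17398 of the 17572 gene identifiers matched. Exons of 41 of 138 genes checked overlapped an exon of another annotated gene, and their counts can include reads of that gene.

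Summed counts per library ran from 20375395 to 27859889, so 1 count was worth at most 0.04908 CPM. Intervals and floors from counts cover counting error only. No pair of libraries within a group was as alike as sampling noise alone would make it, since the chi-square per gene with at least 50 counts in the pair lay between 14.2 and 106.8, so no library was a copy of another. This does not show separate animals; all 3 libraries of a group were counted as replicates because the labels list them as separate samples. The Y-linked gene Ddx3y had 0 or 1 count in each library.

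Differences between HS and NS were tested with edgeR 4.0.16 in R 4.3.3 on the counts. Genes were kept by filterByExpr with the groups (minimum count 10), which left 14513 genes and removed 3059. Libraries were scaled by TMM, with factors between 0.955 and 1.033. A quasi-likelihood model (glmQLFit, glmQLFTest, robust) with the group as the only term gave log2 fold changes, their standard errors and p-values, adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The common biological coefficient of variation was 0.19. CPM values are normalised by the TMM-scaled library totals. All choices named in this paragraph and the next were made before the data were examined.

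A total of 45 gene lists covering matrix, signalling, inflammation, cell state, tissue quality, body position and cell types was fixed, of which 940 of 981 entries were in the table. Lists with at least 5 tested members, 43 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists. The B and plasma cell list and the sex-linked list had fewer. Camera called 31 lists, 24 higher and 7 lower in HS. With an estimated correlation it called none, with a smallest adjusted p of 0.2362, and fry called 4 (both Hox lists, mast cells and secretory genes). Fry's mixed test called 38. Camera compares a list with other genes, while fry does not. Calls per list were also counted with the adjustment over the list alone.

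The rule for naming genes took 8 genes whatever their result (Col1a1, Col3a1, Fn1, Postn, Acta2, Tgfb1, Ccn2, Lox), the 6 largest rises and 6 largest falls among called genes with no overlap between groups and a mean of at least 10 CPM in the higher group, and the called lists' members with the smallest p up to 40 genes, 2 a list and 3 for matrix, signalling and position lists. Lists without a call could be described by their 2 members with the smallest p. Every other gene, including the examples from lists ranked after the 40 genes were reached, was chosen after its values were seen.

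The procedure was tested on simulated negative binomial counts for 14513 genes with the means and library sizes of the HS and NS comparison. The 200 changed genes were drawn from those with a mean of at least 1 CPM, so recovery at lower expression was not measured. It recovered 40.3% of 67 genes changed 1.5-fold, 62.7% of 67 changed 2-fold and 90.9% of 66 changed 4-fold, and 9 of its 138 calls (6.5%) were false. The simulation gave both groups the same dispersion for each gene, drew genes independently and held no outlying library. In the data the chi-square per gene was 47.9 to 106.8 between HS libraries and 14.2 to 20.7 between NS libraries. The simulated rates may therefore not hold for this comparison. Alternatives were DESeq2-type size factors, no factor beyond the total, no filter or at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, no robust step, a minimum log2 fold change of 1, and totals without muscle, hair, blood and mitochondrial genes. Thinning every library to 20375395 counts was added after seeing the data. Terms of the Gene Ontology in the table's own annotation, with 10 to 500 tested genes, were tested after the results were seen by a one-sided hypergeometric test (Python 3.11.15, scipy 1.17.1) against the annotated tested genes.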

Results

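The series profiled skin scars of wild-type C57BL/6 mice by RNA sequencing, 2 weeks after wounding. Hypertrophic scars (HS, n = 3 libraries) formed on the upper back, where the wound edges had been stretched and stitched to the rib cage. Normal scars (NS, n = 3 libraries) formed on the lower back, where the wound had been closed in place without tension. The comparison of HS with NS asks how the transcriptome of a scar formed under tension differs from that of a scar formed without it. Tension and position on the back changed together between the groups, so every difference described here is a difference between both. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

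The count table held 17572 protein-coding genes. The summed counts were 27859889, 22442713 and 27753548 in HS replicates 1, 2 and 3 and 22154858, 20375395 and 24828715 in NS replicates 1, 2 and 3, so that 1 count was worth between 0.03589 and 0.04908 CPM (counts scaled to the library total). Col3a1, which encodes the main chain of type III collagen, took the most counts of any gene in each HS library (2.73%, 1.21% and 2.11% of the total). Tchh, a protein of the hair root sheath, led in NS replicates 1 and 2 (1.36% and 1.14%), and Krt10, a keratin of the upper epidermis, in NS replicate 3 (1.18%). The first principal component of log2 CPM held 53.3% of the variance and separated the groups, with scores of 57.8, 10.2 and 40.5 in HS replicates 1 to 3 and between -38.7 and -33.5 in the NS libraries. HS replicate 2 thus lay nearest to NS, and across genes its log2 CPM correlated more with each NS library (r between 0.967 and 0.973) than with HS replicate 1 (0.965), and most with HS replicate 3 (0.982).

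**Figure D1:**
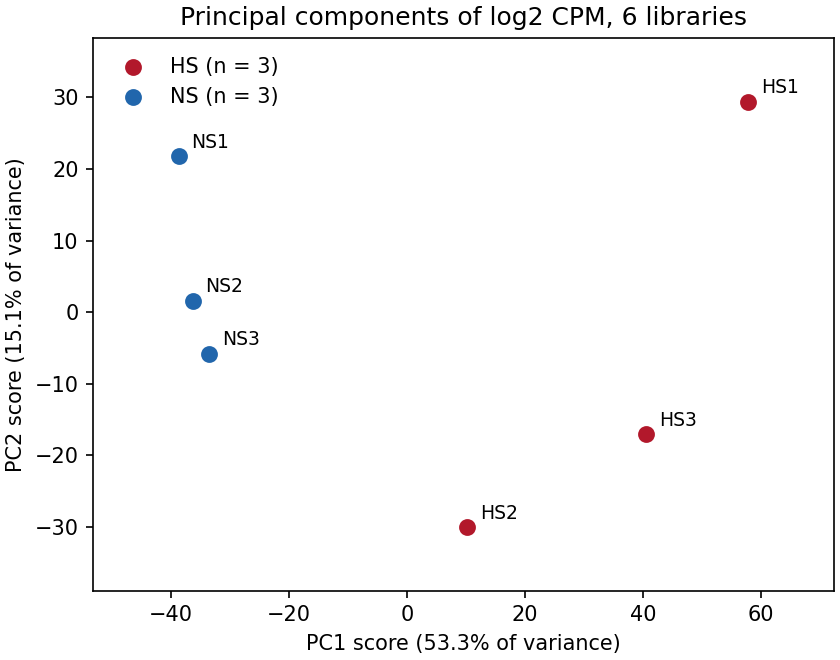
Principal components 1 and 2 of log2 CPM, with each point 1 library, coloured by group and named by group and replicate. The 3 NS libraries sit between -38.7 and -33.5 on the first component, and HS replicate 2, at 10.2, is the HS library nearest to them.

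Most called genes of the fibrous matrix, of matrix proteases, of blood vessels and of neutrophils were higher in HS, and the called posterior Hox and sebaceous gland genes were lower. Camera called these groups as lists at a preset correlation but no list with an estimated correlation (smallest adjusted p = 0.2362 with an estimated correlation), so the list calls are descriptive. Of 14513 genes tested, 1284 differed between HS and NS, 919 of them higher in HS and 365 lower. The changes upward were larger, since 540 of the higher genes and 56 of the lower genes moved by at least 1 on the log2 scale. The 3 HS and 3 NS values did not overlap for any of the 1284 called genes. Among all tested genes 32.3% did not overlap, against 10% by chance.

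The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3810 genes had an unadjusted p below 0.05. The count of calls depended on single libraries. It was 1084 without HS replicate 1, 3257 without HS replicate 2, 148 without HS replicate 3, 94 without NS replicate 1, 25 without NS replicate 2 and 48 without NS replicate 3, and the distinct called members of the gene lists numbered between 12 and 420 in these fits, against 231 with all libraries (365 with DESeq2). Single genes depended on them too. Of 138 genes checked, some never called, 11 lost their call without HS replicate 1, 3 without HS replicate 2 and 71 without HS replicate 3. Without NS replicates 1, 2 and 3, 85, 102 and 98 lost it. Col1a1, Col3a1, Fn1 and Lox each lost their call in 4 of 17 alternatives, and Postn in 5. With no normalization factor beyond the library total, the split was 930 higher and 585 lower, or 61.4% higher in place of 71.6%.

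The 6 largest rises among well-expressed genes were in Brinp3, S100a9, Tnn, Cxcl5, Spp1 and Clec4e. Brinp3 (chromosome 1, 146494760 to 146902472) rose from 0.418 ± 0.189 to 13.9 ± 6.61 CPM (mean ± SD, n = 3), and Tnn, which encodes the matrix protein tenascin N (chromosome 1, 160085029 to 160153580), from 9.81 ± 2.34 to 266 ± 132 CPM. S100a9, a subunit of the neutrophil protein calprotectin, was 31.1-fold higher in HS, and the neutrophil-attracting chemokine Cxcl5 was 24.2-fold higher. Spp1, which encodes osteopontin, was 22.8-fold higher, and Clec4e, a receptor of innate immune cells, 19.8-fold higher. edgeR adjusted p-values of these 6 genes lay between 0.004647 for Brinp3 and 0.04198 for Clec4e. HS replicate 1 carried much of the rise in Cxcl5 and Clec4e, whose log2 fold changes were 3.56 and 3.36 without it, against 4.59 and 4.30 with it. With limma-voom neither passed (adjusted p = 0.161 and adjusted p = 0.175), nor with no filter on low counts (adjusted p = 0.0541 and adjusted p = 0.0815). The log2 fold change of S100a9 was 4.35 without HS replicate 3, against 4.96.

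The 6 largest falls were in Hoxb9, Krt2, Hoxa9, Retnla, Fcna and Hoxa7. Krt2, a keratin of the upper epidermis, fell from 20.6 ± 4.53 to 2.18 ± 0.484 CPM (SD, n = 3, edgeR adjusted p = 0.001648). Retnla, a secreted protein made by alternatively activated macrophages, fell from 94.2 ± 14.9 to 10.2 ± 6.23 CPM (adjusted p = 0.01364). Fcna, a ficolin of the lectin complement pathway, fell from 11.6 ± 1.91 to 2.68 ± 1.67 CPM (adjusted p = 0.02162). Without HS replicate 1 the falls were larger in Hoxb9 (log2 fold change -4.05, against -3.26), Retnla (-3.80, against -3.19) and Fcna (-2.72, against -2.10). The exons of Fcna and of Hoxa7 each overlap those of an antisense gene, and those of Hoxa9 overlap a microRNA gene on the same strand. The strand used in counting is not given in the sources used here.

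Of 11 fibrillar collagens and associated collagens tested, 8 rose in HS, with none lower and a median log2 fold change of 1.5. Col1a1, the gene of the main chain of type I collagen (chromosome 11, 94936224 to 94953042), rose 2.64-fold, from 3101 ± 531.8 to 8173 ± 2594 CPM (SD, n = 3, edgeR adjusted p = 0.01823). Col3a1 (chromosome 1, 45311538 to 45349706) rose 4.05-fold, to 20720 ± 8248 CPM (adjusted p = 0.01255), and Col1a2 and Col5a2, chains of type I and type V collagen, rose 2.70-fold and 3.86-fold. Adjusted over the list alone, 9 of the 11 passed. As a list the fibrillar collagens were higher at an adjusted camera p of 1.977e-11, a call lost with an estimated correlation (adjusted p = 0.2527 with an estimated correlation). The mean log2 difference of the list from NS was 1.59, 0.78 and 1.46 in HS replicates 1 to 3.

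Of 31 glycoproteins and proteoglycans of the matrix, 20 rose, none fell and 11 were not called, and 25 passed when adjusted over the list alone. Fn1, which encodes fibronectin (chromosome 1, 71585520 to 71653200), rose 3.98-fold (log2 fold change 1.99 ± 0.363, SE, adjusted p = 0.02700), and Postn, which encodes periostin (chromosome 3, 54361109 to 54391037), rose 4.55-fold (2.19 ± 0.355, adjusted p = 0.02013). The small proteoglycan Aspn rose 4.97-fold, the microfibril gene Fbn2 2.90-fold and Mfap4 2.21-fold. The camera call of this list (adjusted p = 2.102e-31) was lost with an estimated correlation (adjusted p = 0.2527 with an estimated correlation). Of 17 basement membrane, beaded and other collagens, 7 rose, among them Col7a1 (2.35-fold), Col8a1 (2.59-fold) and Col6a3 (3.04-fold), and 1 fell, Col4a6, a chain of epithelial basement membranes (log2 fold change -0.60). Adjusted over the list alone, 12 passed, 10 higher and 2 lower. That list's camera call (adjusted p = 5.378e-05) was lost as well (adjusted p = 0.3363 with an estimated correlation).

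Of 24 genes of collagen folding and cross-linking, 13 rose, none fell and 11 were not called, and 20 passed when adjusted over the list alone, 19 of them higher. Lox, which encodes lysyl oxidase, the enzyme that starts the cross-linking of collagen and elastin (chromosome 18, 52516067 to 52529867), rose 3.20-fold, from 173 ± 3.20 to 554 ± 193 CPM (SD, n = 3, adjusted p = 0.01542). Serpinh1, the collagen chaperone HSP47, rose 2.62-fold, and P4ha3, a prolyl hydroxylase subunit, 7.92-fold (adjusted p = 0.0549 with limma-voom). The list's adjusted camera p was 1.717e-13, not kept with an estimated correlation (adjusted p = 0.2917 with an estimated correlation). Matrix proteases and their inhibitors rose at the same time, 16 of 27 higher and none lower, with 24 passing when adjusted over the list alone. Mmp13, an interstitial collagenase, rose 13.7-fold to 37.4 ± 9.95 CPM and had the smallest p of the whole test (adjusted p = 0.001648). The macrophage elastase Mmp12 rose 9.33-fold, and the protease inhibitor Serpine2 2.25-fold. The call of this list (adjusted camera p = 2.742e-22) was lost with an estimated correlation (adjusted p = 0.2527 with an estimated correlation). HS replicate 2 had the smallest mean rise of the HS libraries in each of these 5 lists, 0.96 for the proteases against 1.9 in HS replicate 1 and 1.71 in HS replicate 3.

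**Figure D2:**
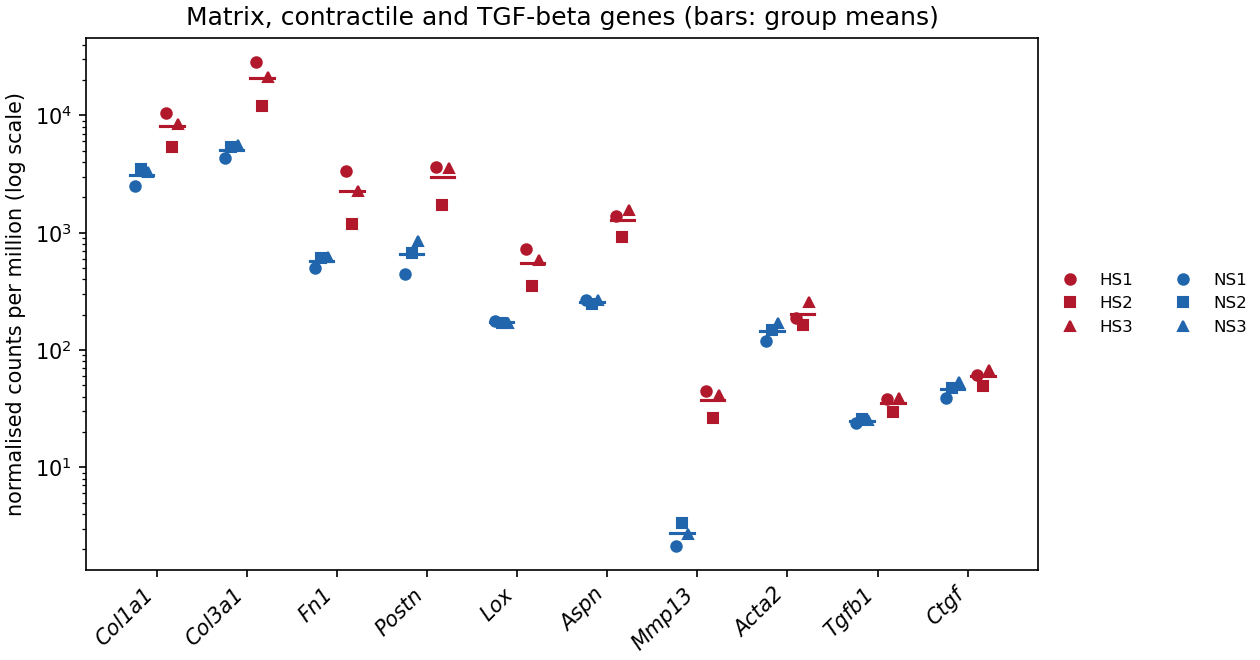
Normalised CPM on a log axis for 10 genes, with 1 point per library and a bar at each group mean (n = 3). Col1a1, Col3a1, Fn1, Postn, Lox, Aspn and Mmp13 lay higher in all HS libraries than in all NS libraries and were called, while Acta2, Tgfb1 and Ctgf, at 1.39-fold, 1.43-fold and 1.27-fold, were not called.

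Some contractile and TGF-beta genes were higher in HS. Of 21 contractile genes of the smooth muscle type, 8 rose, among them Mylk (1.63-fold), Tpm4 (1.5-fold) and Myh11 (1.77-fold), and none fell, with 10 passing when adjusted over the list alone. Acta2, the usual marker of myofibroblasts (chromosome 19, 34241090 to 34255590), stood at 203 ± 47.6 CPM in HS and 146 ± 25.6 CPM in NS (SD, n = 3), a 1.39-fold difference that did not pass (edgeR adjusted p = 0.1601). Of 26 genes of the TGF-beta pathway, 7 rose and none fell, and 9 passed when adjusted over the list alone. The ligand Tgfb3 rose 2.14-fold, the latent binding protein Ltbp2 3.14-fold and Lrrc32, which presents latent TGF-beta on cell surfaces, 2.74-fold. Tgfb1 (chromosome 7, 25687002 to 25705077) was 1.43-fold higher without passing (adjusted p = 0.05222), and Ctgf (Ccn2), a common TGF-beta and YAP target (chromosome 10, 24595442 to 24598683), 1.27-fold higher without passing (adjusted p = 0.1841). Without HS replicate 2, Tgfb1 and Ctgf passed, at adjusted p = 0.00445 and adjusted p = 0.0289, and Tgfb1 also passed with DESeq2 (adjusted p = 0.0132) and with no filter on low counts (adjusted p = 0.0486). The camera calls of the contractile list (adjusted p = 1.591e-05) and of the TGF-beta list (adjusted p = 5.378e-05) were both lost (adjusted p = 0.3363 with an estimated correlation for each).

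Genes of stretch sensing, focal adhesions and YAP/TAZ went both ways. Of 37 tested, 10 rose and 2 fell, and 21 passed when adjusted over the list alone, 17 higher and 4 lower. The stretch-activated channel Piezo2 rose 4.05-fold, the collagen-binding integrin chain Itga11 2.74-fold and the integrin chain Itgb1 1.89-fold. The 2 that fell were the channel Trpv4 (log2 fold change -0.64) and Ankrd1, a YAP target that is also expressed in striated muscle (-1.35, from 36.8 ± 9.49 to 14.5 ± 5.19 CPM). The list's adjusted camera p was 0.0005967, lost with an estimated correlation (adjusted p = 0.4376 with an estimated correlation). Of 35 Wnt genes, 5 rose and 2 fell, with Wnt16 5.37-fold, the Wnt inhibitor Sfrp2 13.2-fold and Dkk3 1.89-fold higher; Sfrp2 had a log2 fold change of 3.04 without HS replicate 1, against 3.73. The Wnt list was not called by camera (adjusted p = 0.1343). Its median, -0.27, and its mean, 0.11, differed in sign, and 15 passed when adjusted over the list alone, 6 higher and 9 lower. Without HS replicate 2, 7 Wnt genes were called higher and 12 lower.

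Of 21 endothelial markers, 11 rose and none fell (17 when adjusted over the list alone), with a median log2 fold change of 1.17. Pecam1, an adhesion molecule of endothelial cells, rose 2.96-fold, from 35.1 ± 2.81 to 104 ± 27.2 CPM (SD, n = 3, edgeR adjusted p = 0.008279), and the VEGF receptor Kdr 2.20-fold. Of 29 growth factor and angiogenesis genes, 10 rose and none fell (16 over the list alone), among them Angpt2 (4.67-fold) and the VEGF receptor Flt1 (2.00-fold). Of 16 pericyte and vascular smooth muscle markers, 5 rose, including Rgs5 (2.42-fold) and Kcnj8 (3.67-fold, adjusted p = 0.0522 with limma-voom), and 1 fell, Cspg4 (log2 fold change -0.44); adjusted over the list alone, 7 were higher and 1 was lower. The adjusted camera p-values of the endothelial, growth factor and pericyte lists were 2.87e-15, 9.427e-09 and 0.002077, and each call was lost with an estimated correlation (adjusted p = 0.2527, adjusted p = 0.2917 and adjusted p = 0.3363 with an estimated correlation).

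Neutrophil markers had the highest median of all lists. Of 11 neutrophil markers tested, 7 rose and none fell (9 when adjusted over the list alone), with a median log2 fold change of 3.16. The median was 3.16 with no filter on low counts (19 tested). With at least 1 CPM in 3 libraries it was 2.38 (5 of 8 higher). Retnlg, with no count in any NS library, lay above the median also at its bound, so setting it there could not move the median. Retnlg had 48, 16 and 23 counts in HS replicates 1 to 3 and was at least 25.6-fold higher, against a floor of 3 counts over the NS group. Irg1 (Acod1), an enzyme of activated myeloid cells, had 275, 48 and 195 counts in HS and 2, 0 and 0 counts in NS. Of 27 cytokines and chemokines, 7 rose and 1 fell (14 and 1 over the list alone), while limma-voom called 1 and DESeq2 15. The mean cytokine difference from NS was 2.05, 0.36 and 1.23 in HS replicates 1 to 3. Il33, an alarmin, rose 3.76-fold, from 30.4 ± 5.21 to 114 ± 17.0 CPM (SD, n = 3, adjusted p = 0.001836), and the neutrophil chemokine Cxcl2 40.1-fold (log2 fold change 5.33, and 6.01 without NS replicate 2; adjusted p = 0.0838 with limma-voom), while the B cell chemokine Cxcl13 was the 1 that fell (log2 fold change -2.79; adjusted p = 0.0758 with limma-voom). The calls of the neutrophil list (adjusted camera p = 2.559e-10) and of the cytokine list (adjusted camera p = 3.086e-06) were lost (adjusted p = 0.2527 and adjusted p = 0.3823 with an estimated correlation).

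Some markers of other immune cells were higher in HS. Of 21 macrophage and monocyte markers, 5 rose and none fell (13 over the list alone), with Cx3cr1 4.98-fold and Trem2 5.65-fold higher. Of 11 mast cell markers, 6 rose (7 over the list alone), including the chymase Mcpt4 (1.53-fold) and Hpgds (2.09-fold). In the interferon list 5 of 26 genes rose (11 over the list alone), with the transcription factor Irf1 2.12-fold higher (adjusted p = 0.0504 with limma-voom). That count was 4 with no filter on low counts and 17 without HS replicate 2. In the T and NK cell list 1 of 18 rose, Cd4 (3.10-fold; adjusted p = 0.0739 with limma-voom), and in the dendritic and Langerhans list 1 of 15, Itgax (4.69-fold), with 1 each over the list alone. Of 23 complement and coagulation genes 4 rose (6 higher and 1 lower over the list alone), including F7 (8.13-fold) and Tfpi (2.20-fold). The adjusted camera p-values of these 6 lists, in the order given, were 5.445e-07, 9.713e-05, 7.681e-07, 0.0008267, 0.03519 and 0.006067, and each call was lost with an estimated correlation (adjusted p = 0.3615, adjusted p = 0.2362, adjusted p = 0.4677, adjusted p = 0.3363, adjusted p = 0.4677 and adjusted p = 0.5 with an estimated correlation). The complement list was not called without HS replicate 1 (adjusted p = 0.182), nor was the dendritic list without HS replicate 1 (adjusted p = 0.184), HS replicate 2 (adjusted p = 0.0728) or NS replicate 1 (adjusted p = 0.149), or with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0729). The mean interferon list difference from NS was 2.04 in HS replicate 1, 0.17 in HS replicate 2 and 0.75 in HS replicate 3. Of the 16 type 2 immunity genes, 3 rose, with the IL-33 receptor Il1rl1 9.65-fold higher (log2 fold change 3.27, and 2.62 without HS replicate 1; adjusted p = 0.0501 with limma-voom), and Retnla was the 1 that fell (5 and 2 over the list alone; 3 higher and 4 lower without HS replicate 1); the list was not called (adjusted p = 0.6741). Of 4 B and plasma cell markers tested, too few for a list test, Igj (Jchain) rose 6.69-fold.

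**Figure D3:**
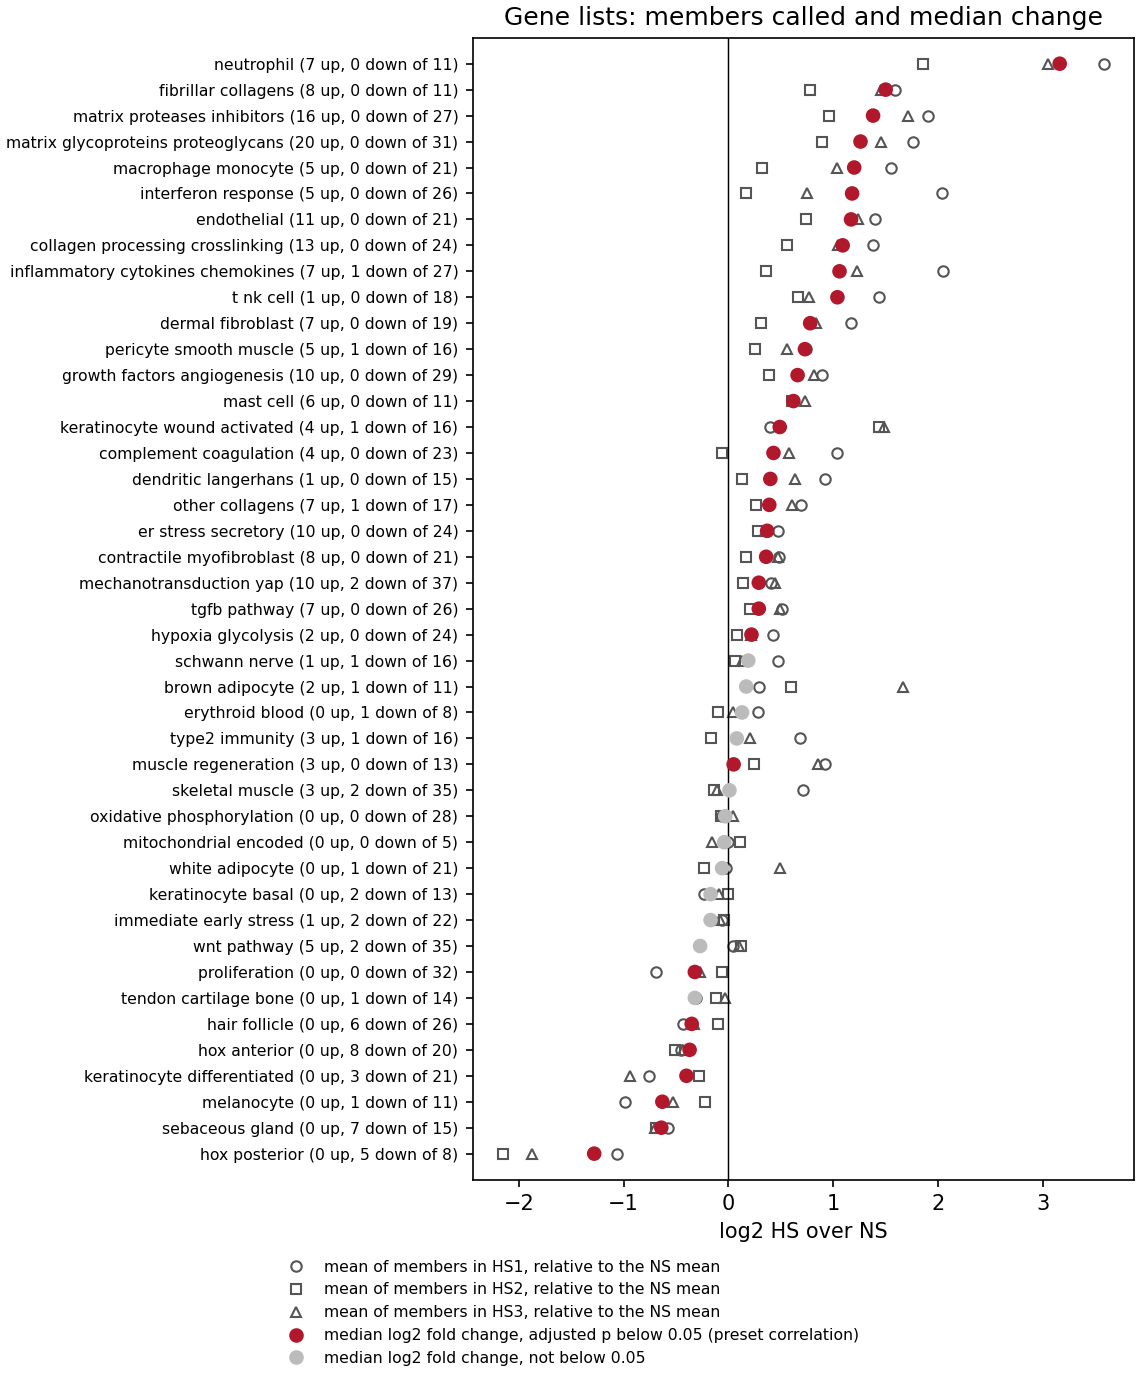
Median log2 fold change of each of 43 gene lists with at least 5 tested members (filled points, red where the adjusted camera p with a preset correlation was below 0.05), with the mean of the members in each HS library relative to the NS mean (open points) and the called members counted beside each name. HS replicate 2 (squares) lies nearest to 0 in most lists that rise, as at 0.78 for the fibrillar collagens against 1.59 and 1.46, but at 1.44 for the wound keratinocyte list it lies beyond HS replicate 1, at 0.4.

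The called genes of sebaceous glands, hair follicles and differentiated keratinocytes were lower in HS. Of 15 sebaceous gland genes, 7 fell and none rose (14 over the list alone), with Fa2h, a fatty acid hydroxylase, falling from 371 ± 39.3 to 200.9 ± 41.03 CPM (SD, n = 3, edgeR adjusted p = 0.01758) and the elongase Elovl3 from 207 ± 29.6 to 127 ± 16.4 CPM. Of 21 genes of differentiated keratinocytes, 3 fell, Krt2, Lce1b and Lor (7 over the list alone). Lce1b, at 0.5003 of the NS level, belongs to a family of near-identical genes whose reads the counting could have divided, and Lor stood at 0.509 of the NS level (adjusted p = 0.0657 with no filter on low counts). Of 26 hair follicle genes, 6 fell (10 over the list alone), including the hair follicle keratin gene Krt72 and the deiminase Padi3 (0.709 and 0.697 of the NS level). Of 11 melanocyte genes, 1 fell, Pmel (log2 fold change -0.94, adjusted p = 0.0548 with no filter on low counts; 1 over the list alone). The adjusted camera p-values of the sebaceous, differentiated keratinocyte, hair follicle and melanocyte lists were 2.291e-10, 4.848e-09, 2.853e-05 and 0.0001669, each lost with an estimated correlation (adjusted p = 0.2527, adjusted p = 0.3363, adjusted p = 0.4593 and adjusted p = 0.3823 with an estimated correlation). The sebaceous list lay at -0.58, -0.69 and -0.70 in HS replicates 1 to 3, so HS replicate 2 did not lie nearest to NS for these genes.

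Genes of activated wound-edge epidermis rose in part. Of 16 tested, 4 rose, among them Sprr2d (17.4-fold; log2 fold change 4.12, and 4.95 without NS replicate 1) and Krt6b (13.2-fold), 1 fell, S100a7a (log2 fold change -0.50), and 11 were not called (7 higher and 3 lower over the list alone). Without HS replicate 2 the balance turned, with 1 called higher and 3 lower and a median of 0.21, against 0.49 with it. Krt6b stood at 846 ± 532 CPM in HS and 64.2 ± 27.7 CPM in NS (adjusted p = 0.051 with no filter on low counts). The Sprr2 genes are near-identical copies, so the reads assigned to each are uncertain. The list's adjusted camera p of 0.01152 was lost with an estimated correlation (adjusted p = 0.4808 with an estimated correlation) and also without HS replicate 2 (adjusted p = 0.751). Of 13 basal keratinocyte genes, Krt5 (0.713 of the NS level) and Cdh3 (0.675 of the NS level) fell (2 over the list alone), and the list was not called (adjusted p = 0.1356).

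Of 19 dermal fibroblast markers, 7 rose and none fell (11 higher and 1 lower over the list alone). Crabp1, a retinoic acid binding protein, rose 3.60-fold, from 9.16 ± 0.393 to 32.9 ± 6.93 CPM (SD, n = 3, adjusted p = 0.002353), and the hyaluronan synthase Has2 2.46-fold. The list's call (adjusted camera p = 3.884e-08) was lost (adjusted p = 0.3363 with an estimated correlation). Secretory and unfolded protein response genes rose in 10 of 24 members (16 over the list alone), with Pdia4 1.37-fold, Kdelr2 1.52-fold and Kdelr3, the largest, 2.88-fold higher and an adjusted camera p of 1.069e-06, lost with an estimated correlation (adjusted p = 0.2917 with an estimated correlation). Of 24 hypoxia and glycolysis genes, Hif1a (1.46-fold) and Ndrg1 (1.33-fold) rose (2 over the list alone). Ndrg1, at adjusted p = 0.0476, kept its call only without HS replicate 2 when 1 library was left out, with adjusted p otherwise between 0.0814 (without HS replicate 1) and 0.173 (without NS replicate 1), and its call was also lost with limma-voom (adjusted p = 0.0619), no normalization factor (adjusted p = 0.061) and no robust step (adjusted p = 0.0525). For the list, the call (adjusted camera p = 0.006384) was lost with an estimated correlation (adjusted p = 0.4677 with an estimated correlation) and without HS replicate 1 (adjusted p = 0.0703).

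No gene of DNA synthesis or mitosis passed edgeR's test, 0 of 32 (0 over the list alone), and the list's median was -0.32. Without HS replicate 2, 18 of the 32 were called lower, and DESeq2 called 2 lower; no normalization factor, no filter on low counts and thinned libraries gave 1 each. Aurkb had a log2 fold change of -0.56 (adjusted p = 0.05387) and Ccnb2 of -0.44 (adjusted p = 0.07276). The list was lower by camera (adjusted p = 2.213e-06), not with an estimated correlation (adjusted p = 0.4677 with an estimated correlation), and its mean difference from NS was -0.69, -0.06 and -0.27 in HS replicates 1 to 3.

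Hox genes, which mark position along the body axis, differed between the groups. Of 8 Hox genes of paralogue groups 9 to 13 tested, 5 fell in HS and none rose (5 over the list alone). Hoxc13, 1 of the 5, fell least (log2 fold change -0.56, edgeR adjusted p = 0.0422) and is also a member of the hair follicle list. Hoxa9 (chromosome 6, 52223100 to 52231089) fell from 19.0 ± 1.78 to 2.02 ± 0.722 CPM (SD, n = 3, edgeR adjusted p = 0.001648), and Hoxb9 (chromosome 11, 96271457 to 96276595) from 15.8 ± 2.32 to 1.63 ± 1.23 CPM (adjusted p = 0.01261). Hoxc10 (chromosome 15, 102966796 to 102971893) had 82, 79 and 61 counts in NS replicates 1 to 3 and 6, 1 and 0 counts in HS replicates 1 to 3, so its fold was poorly fixed (log2 fold change -5.08, -7.00 without HS replicate 1 and -4.49 without HS replicate 3). Of 20 Hox genes of groups 1 to 8, 8 fell and none rose (9 over the list alone), among them Hoxa7, Hoxb8 and Hoxa5 at 0.248, 0.379 and 0.509 of the NS level. Both Hox lists were lower by camera (adjusted p = 1.247e-08 for groups 9 to 13 and adjusted p = 5.597e-06 for groups 1 to 8), and fry, which asks whether a list moves one way, called both as well (adjusted p = 0.01356 for each). The camera calls were lost with an estimated correlation (adjusted p = 0.2362 with an estimated correlation for each).

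**Figure D4:**
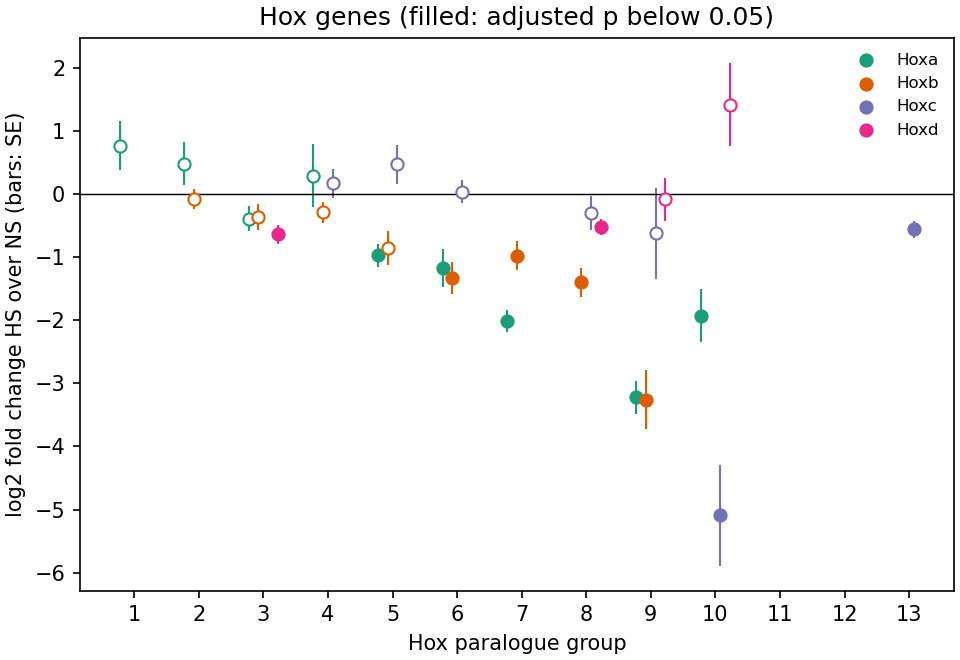
Log2 fold change, HS over NS, with its standard error for each of 28 tested Hox genes, placed by paralogue group and coloured by cluster; filled points were called. Hoxc10, at -5.08, had the largest fall, and the 2 genes of groups 1 to 5 that were called, Hoxa5 and Hoxd3, had -0.97 and -0.64.

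Skeletal muscle genes did not move as a list, but the myosins exchanged places. Of 35 fibre genes, 3 rose and 2 fell (5 and 3 over the list alone), with a median log2 fold change of 0.01 and an adjusted camera p of 0.8299. Myh4, the myosin heavy chain of fast type IIb fibres, rose 9.36-fold, from 132 ± 20.7 to 1236 ± 445.1 CPM (SD, n = 3, adjusted p = 0.004612), while Myh2, that of type IIa fibres, fell from 561 ± 111 to 185 ± 26.0 CPM (adjusted p = 0.004612). Myh1, that of type IIx fibres, stood at 1854 ± 815.0 CPM in HS and 1847 ± 350.9 CPM in NS (adjusted p = 0.9925). Once HS replicate 1 was left out, 6 fibre genes were called higher and 14 lower, with a median of -0.37, and camera called the list lower in HS (adjusted p = 0.000242). Of 13 satellite cell and regeneration genes, 3 rose, Myh8 (3.18-fold), Tmem8c (Mymk, 7.26-fold) and Gm7325 (Mymx), and none fell (5 over the list alone). The regeneration list's call (adjusted camera p = 0.02651) was lost with an estimated correlation (adjusted p = 0.4677 with an estimated correlation) and without HS replicate 1 (adjusted p = 0.196), with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.151) and with thinned libraries (adjusted p = 0.0537).

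**Figure D5:**
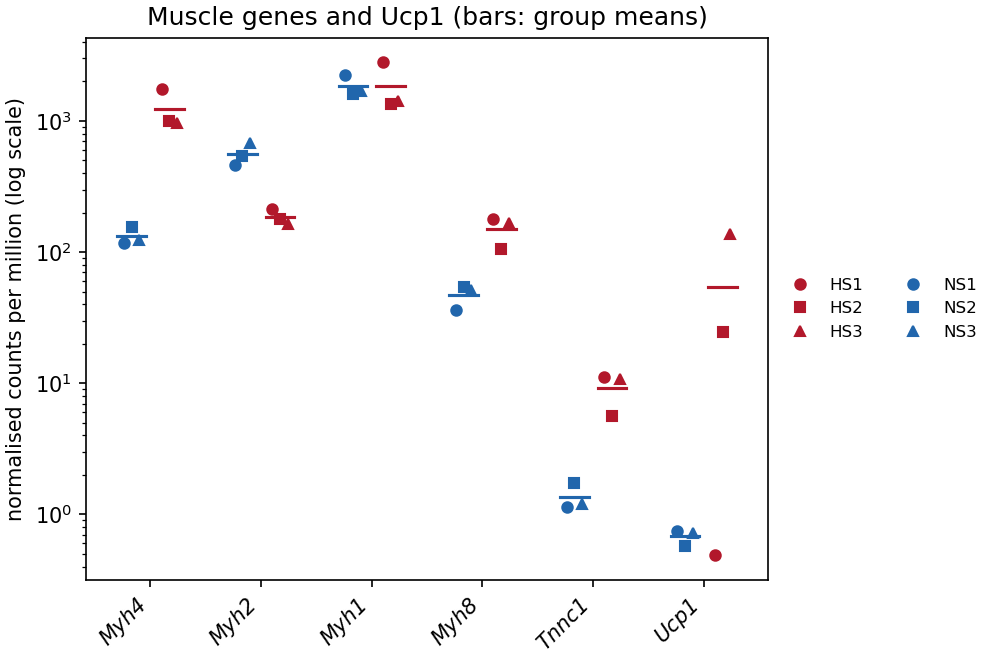
Normalised CPM on a log axis for 6 genes, with 1 point per library and a bar at each group mean (n = 3). Myh4 lay higher and Myh2 lower in all HS libraries, Myh1 overlapped, and Ucp1, which was not called, spread over the HS libraries from 0.489 to 138 CPM.

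The remaining lists were not called by camera. Adjusted p-values were 0.2291 for respiratory chain subunits (0 of 28 called, also over the list alone), 0.7547 for mitochondrially encoded genes (0 of 5), 0.1292 for immediate early and stress genes (1 higher, and Egr3 and Egr2 lower, of 22, and the same over the list alone), 0.6482 for white adipocytes (1 of 21, Dgat2 at 0.708 of the NS level), 0.4196 for brown adipocytes (2 higher and 1 lower of 11, and 3 higher and 1 lower over the list alone), 0.1356 for tendon, cartilage and bone (1 of 14, Alpl, lower), 0.6741 for Schwann cells and nerve (1 higher, Scn7a, and 1 lower, Egr2, of 16, and 2 higher and 1 lower over the list alone) and 0.7547 for red cell genes (1 of 8, Slc4a1, lower). The median and the mean differed in sign for white adipocytes (-0.06 and 0.11), and the red cell list had a median of 0.13 and a mean of 0.04 with a downward test. The immediate early list was called without NS replicate 1 (adjusted p = 0.00216), the white adipocyte list without HS replicate 3 (adjusted p = 0.00414), and the tendon, cartilage and bone list with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0201). Adjusted over the list alone, white adipocytes, tendon and red cells kept 1 called gene each.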

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

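Each alternative here was planned except the thinning of libraries, which was chosen after the data were seen. No gene called in HS against NS changed direction under any alternative in which it was tested. Leaving out 1 library gave between 25 calls (without NS replicate 2) and 3257 (without HS replicate 2), with 20 to 2000 higher and 5 to 1257 lower, and 12 to 420 called members of the gene lists; a fit on 5 libraries has fewer samples, and the cause of the rise without HS replicate 2 was not tested. DESeq2 called 2435 genes, 1614 higher and 821 lower, with 365 list members, and kept all 1284. A minimum log2 fold change of 1 left 596, 540 higher and 56 lower, with 148 list members, by construction. Dropping the TMM factors shifted the median log2 fold change by -0.059 by construction, since they lay at or below 1 in HS and above 1 in NS, and 585 genes were then called lower. The other settings, size factors, both filters, limma-voom, no robust step, totals without muscle, hair, blood and mitochondrial genes, and thinned libraries, gave between 945 calls (limma-voom) and 1355 calls (no robust step). Gene list tests gave 28 to 32 lists without 1 library, 30 or 31 under the other normalizations, filters and thinning, 0 with an estimated inter-gene correlation and 4 by fry, which asks another question; the cause was not tested beyond that. The skeletal muscle list turned from no call to lower in HS without HS replicate 1 (adjusted p = 0.000242, up to 0.897 without NS replicate 3); in that library the fibre genes lay 0.71 above the NS mean.

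Samples share a number but no stated origin. The numbers were not taken to pair samples, because the labels do not say that equal numbers share an animal. Deviations of same-numbered libraries from their group means correlated at 0.01, 0.01 and 0.03. With 3 libraries a group, such values cannot exclude a shared animal. With the replicate block, 1001 genes were called (730 higher and 271 lower, 203 list members) and 31 lists, and 879 of the 1284 calls remained. Depth limits genes near 1 count per library; thinning to the smallest total kept 1221 of the 1280 calls that were still tested.

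The 6 libraries can be split in 10 ways into 2 groups of 3, too few for a share under 0.05. The real split gave 1284 calls, 919 higher and 365 lower, and it was the 1 split with as many of each; the highest of the others was 0. For gene lists 2 of the 10 splits gave as many, since the split of HS replicates 1 and 3 with NS replicate 3 against the rest also gave 31. Every other split had HS and NS libraries on both sides. Part of the HS and NS difference therefore stayed between its sides, and part entered the spread within them. This favours 0 called genes, so these splits do not show that the real calls exceed chance. Splits with 0 called genes gave between 9 and 31 lists, so camera at the preset correlation called lists without any called gene. These lists can reflect the remaining difference and are not a measure of false calls. The list calls are descriptive.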

Other observations

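Gene Ontology terms, tested after the results were seen, add sterol and lipid synthesis to the genes lower in HS, beside the lipid-making sebaceous gland genes (7 of 15 lower, 14 over the list alone, median log2 fold change -0.64). Among 271 annotated genes lower in HS, 33 belonged to lipid metabolic process against 8.88 expected (adjusted p = 6.08e-08, one-sided hypergeometric test over 1046 terms), and 8 of 19 tested genes of cholesterol biosynthesis were lower against 0.5 expected (adjusted p = 5.91e-06). Among them, Lss, which closes the sterol rings, stood at 91.0 ± 12.4 CPM in HS and 150 ± 9.09 CPM in NS (SD, n = 3, edgeR adjusted p = 0.01087), and Fdps, which makes farnesyl diphosphate, at 102 ± 12.3 and 156 ± 13.1 CPM (adjusted p = 0.01537). Among 651 annotated genes higher in HS, 69 belonged to cell adhesion against 18.53 expected (adjusted p = 2.04e-19) and 26 to angiogenesis against 6.57 expected (adjusted p = 2.97e-07). Adam12, a membrane metalloprotease of mesenchymal cells, stood at 270 ± 85.9 CPM in HS and 43.8 ± 8.81 CPM in NS (adjusted p = 0.009309). The test treats genes as independent, which they are not. Ucp1, the uncoupling protein of brown fat, had 13, 550 and 3754 counts in HS replicates 1 to 3 and 17, 12 and 18 in NS replicates 1 to 3 (edgeR adjusted p = 0.0825, between 0.000897 with DESeq2 and 0.59 with limma-voom).

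The tests on the Hox genes, on muscle, and on the position of HS replicate 2 over the Hox and interferon genes were chosen after the results were seen.

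Of 8 posterior Hox genes 5, with Hoxc13 of the hair follicle list among them, were called lower in HS and 3 (Hoxc9, Hoxd9 and Hoxd10) were not called. The HS wounds lay on the upper back and the NS wounds on the lower back. Across 28 tested Hox genes, which are not independent replicates, the log2 fold change fell with the paralogue group (Spearman's rho = -0.48, permutation p = 0.01; Pearson's r = -0.45, permutation p = 0.016; r = -0.48 without the 2 genes farthest from the median group). The clusters differed. All tested Hoxa and Hoxb genes of groups 6 to 10 were called lower. Hoxc10 was called lower too, but Hoxc6, Hoxc8 and Hoxc9 were not called (log2 fold change 0.04, -0.3 and -0.62). In the Hoxd cluster the values ran the other way, with Hoxd3 at -0.64, Hoxd8 at -0.52, Hoxd9 at -0.08 and Hoxd10 at 1.42, the last 2 not called. The trend over all clusters restates the pattern on the same genes, so it does not test wound position, which stays open. A smaller share in HS of cells that express all Hox groups alike would lower all groups alike. The groups did not fall alike, since the median of the 15 genes of groups 6 to 10 lay 0.98 below that of the 12 genes of groups 1 to 5 (difference of medians -0.98, two-sided permutation p = 0.0069). The contrast uses the same genes as the trend, so its p-value is descriptive. It cannot decide whether cells that express mainly groups 6 to 10 were fewer in HS. Tension as a cause also stays open and was not tested, because it changed with position in every library.

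Myh4 was 9.36-fold higher in HS with Myh2 lower. More skeletal muscle tissue in the HS samples would raise all fibre genes, but the median log2 fold change of 33 other fibre genes, with Myh2 left out as well, was 0.01 (SD over genes 0.82), below the 3.23 of Myh4 by more than 2 SD. Because Myh4 was picked by its size, this argues only against more muscle as the source of a rise that large. The mean of the fibre list lay 0.71, -0.14 and -0.11 from NS in HS replicates 1 to 3, so more muscle in HS replicate 1 was not excluded. Regenerating muscle may have contributed, since Myh8, Tmem8c (Mymk) and Gm7325 (Mymx) rose. However, Myh3 was flat (log2 fold change 0.05), and the median of the 12 regeneration genes without Des was 0.31, with a one-sided p of 0.077 among 10000 random lists of like expression. Some muscle genes outside that list were picked after their values were seen, so they are examples and not a survey. Of these, Actc1 (4.07) and Myl4 (2.39) were called higher. Csrp3 (-1.08), Ankrd2 (-1.67), Ankrd1 (-1.35), Myoz2 (-1.21) and Myom3 (-0.94) were called lower. Regenerating muscle cannot be told apart from other explanations with 3 libraries a group. A different muscle layer under the upper back is a biological alternative that the design confounds with tension and that was not tested.

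HS replicate 2 lay nearest to NS: on a scale where the NS mean is 0 and the mean of HS replicates 1 and 3 is 1, it lay at 0.97 ± 0.08 (SD over resampled genes) for the Hox genes of groups 6 to 10, which argues against a lower-back library under an HS label. It lay at 0.38 ± 0.03 over 110 genes of the matrix lists and at 0.39 after thinning to equal summed counts. Thinning leaves the expected CPM unchanged, so this cannot decide whether the total count played a part. The total of HS replicate 2 (22442713) lay within the range of the NS totals (20375395 to 24828715). A smaller share of scar tissue in that sample could lower the rise of all scar genes, but the lists that fall in HS lay 0.29 further along the scale than the matrix lists, which passed the margin set beforehand by less than its SD of 0.1. As the only cause it would place all rising lists alike. Interferon genes (0.09 ± 0.04) lay at -0.29 ± 0.05 from the matrix. Macrophages (0.23 ± 0.05) and neutrophils (0.26 ± 0.05) also lay lower, and mast cells (0.88 ± 0.14) and wound keratinocytes (1.07 ± 0.13) higher. These SDs take genes as independent, but the interferon list had an estimated correlation of 0.87. The scale also rests on HS replicates 1 and 3, which differed (interferon list 2.04 and 0.75 above the NS mean on the log2 scale). With 1 library in question, the positions cannot decide whether a smaller share of scar tissue was the only cause. As a part of the cause it stays open, with sebaceous glands at 1.02 ± 0.08 and differentiated keratinocytes at 0.53 ± 0.16. An earlier or milder stage of the scar in that sample stays possible and was not tested.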
